A study of Trichoderma virens with 18 samples.

How the data were processed

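The series holds 18 RNA-seq libraries from mycelium of Trichoderma virens strain Gv29-8, a soil fungus that colonises plant roots. Control libraries came from the fungus alone on plates of Murashige and Skoog (MS) medium. Co-culture libraries came from plates on which the roots of 20 Arabidopsis seedlings, 10 days old, were inoculated with the fungus. Mycelium was collected 48, 72 and 96 h after inoculation, with 3 biological replicates of each condition and time, per the labels' protocols. Per the same protocols, strains were maintained at 28 °C on potato dextrose agar, total RNA was taken with TRIzol and treated with DNase, and the libraries were sequenced on the SOLiD platform.

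The deposited values are raw counts of reads per predicted gene of T. virens, 1 column per library, per the file headers. The submitters' processing notes name FastQC 0.11.2, BWA with no version, R 3.0.1 and edgeR 3.2.4, with no role for any of them. The genome build, the annotation release, the counting tool, the strand setting and the handling of reads with several hits are not given in the sources used here. How far reads of the plant were removed from the co-culture libraries is not given either. Members of gene families such as chitinases and kinases, and overlapping genes, are therefore uncertain wherever the counting could have split their reads.

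The table has 12427 genes, of which 213 had no count in any library. Numeric protein identifiers were matched to the locus tags of RefSeq assembly TRIVI v2.0, and 12371 of them matched. The table of that assembly used here holds no column of product names, and 86 genes of the table carried a symbol. Genes without a symbol are given by locus tag. Because the build of the counts is not named, no coordinates are printed, and the assembly served only for names and for the order of genes.

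Total counts per library ran from 2464191 to 11735297. A count of 0 allows up to 3 counts, which is 0.256 CPM in the deepest library and 1.22 CPM in the shallowest. Such floors and the intervals of count ratios (exact binomial, at the 95% level) cover counting error only. No libraries within a group were copies of each other: the lowest chi-square per degree of freedom between libraries of a group was 22.2.

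Differential expression was tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust glmQLFit) on the deposited counts, after TMM scaling and filterByExpr, which kept 9144 genes. All 18 libraries entered 1 model with a mean for each of the 6 groups and 12 residual degrees of freedom. Contrasts compared co-culture with control at each time and as the mean of the 3 times, tested the change of that difference with time (F test), and compared 96 h with 48 h within each condition. The comparisons of 72 h with 48 h and of 96 h with 72 h were chosen after the data were seen. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. CPM values use library totals scaled by TMM and are given as mean ± SD.

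The tests, the alternatives and the rule for named genes were set before the data were examined. That rule took, among called genes with group ranges that did not overlap and a mean of at least 5 CPM, the largest rises and falls, and always the elicitor gene Sm1 and the peptaibol synthetase gene Tex1. Without product names, it allowed at most 2 locus tags that rose and 2 that fell in each comparison. It had no clause for genes with symbols, which here took the place of genes with product names. For the mean of the 3 times it asked for genes called at all 3 times in 1 direction, and no gene met this. The genes named for that comparison were chosen after their values were seen, as called genes with the same direction in 9 of 9 pairs or as members of a symbol group. For 96 h against 48 h, CDK5 and STK2 in control and TVC3 and TVC4 in co-culture lay outside the rule even with symbols allowed. They are named as called members of symbol groups, a choice made after their values were seen.

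The 21 gene lists set beforehand were searches of product names and could not be applied, since none of them matched a symbol. In their place, genes with symbols were sorted into groups of chitinases and glucanases, elicitors, secretory stress genes, G proteins and GTPases, MAP kinases, cyclin-dependent kinases and other kinases, with a few single genes. These groups were written after the symbols were seen and before any test. Groups with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and with fry.

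Replicate numbers recur in every group. Libraries of the same time and number deviated together from their group means. The correlation across genes, which are not independent replicates, ran from 0.138 to 0.502 over the 9 pairs with a median of 0.251. The median for other numbers was −0.0895. Deviations cancel out within a group, so this value mirrors that of equal numbers and is no separate baseline. The labels do not say what a number shares, so the pairing comes from this check of the data. The blocked value is therefore given beside a co-culture result where it changes the call or moves a count by over 1.5 times. The planned block has 1 term per replicate number (10 residual degrees of freedom). A block for each pair within a time (6 residual degrees of freedom) was chosen after the data were seen.

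Alternatives were DESeq2 size factors, upper quartile scaling, library size alone, other filters on low counts, DESeq2 1.42.0, limma-voom, the replicate block, stricter thresholds, leaving out the 20 most abundant genes, thinning to the smallest library, fitting only the groups compared, and leaving out each replicate in turn.

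The procedures were tested on simulated counts with 200 changed genes among about as many tested genes as in the data. For co-culture against control at 48 h (8980 genes), edgeR found 20.8% of genes changed 2-fold and 77.2% of genes changed 4-fold, and 4.02% of its calls were wrong. For the mean of the 3 times (8993 genes) it found 70.8% and 94.4%, with 3.96% wrong calls. DESeq2 found 32% and 84% at 48 h (8985 genes), with 16.2% wrong calls, and 79% and 96% for the mean (9012 genes), with 13.4% wrong calls. The block for each pair found 63.6% and 92.4% for the mean, with 4.23% wrong calls. For the change with time (8991 genes) edgeR found 6.8% of genes changed 2-fold and 50.8% of those changed 4-fold. The set test found the changed set in 20 of 20 simulations of the 48 h comparison and called 0 of 80 unchanged sets at 9144 genes. Rates for calls of genes come from 5 simulations per comparison, and those of DESeq2 from 2. All simulated genes varied independently and libraries were not paired. These rates therefore do not cover paired libraries or sets of correlated genes, such as the chitinase and glucanase group (estimated correlation 0.0568). Figures were drawn with matplotlib 3.10.9.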

Results

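Transcript levels of T. virens were measured in mycelium grown alone or with Arabidopsis seedlings. The 18 libraries form 6 groups of 3 biological replicates, with control and co-culture at 48, 72 and 96 h. Total counts were 3922972 to 6513256 at 48 h, 4105547 to 11735297 at 72 h and 3657705 to 6627744 at 96 h in control. In co-culture they were 3871633 to 5048819 at 48 h, 3933627 to 5562212 at 72 h and 2464191 to 4855695 at 96 h.

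Time separated the libraries more than the plant did. The first principal component of log2 CPM held 46.5% of the variance, and its mean rose from −51.2 ± 27.7 (SD, n = 3) at 48 h to 26.5 ± 5.47 at 72 h and 40.1 ± 7.96 at 96 h in control. In co-culture the corresponding means were −61.9 ± 4.90, 13.4 ± 8.95 and 33.1 ± 4.61. The second component, with 10.8% of the variance, was lower in co-culture in 9 of 9 pairs of libraries of the same time and number, by a mean difference of −30.3 ± 12.5 (SD, exact two-sided permutation within pairs, p = 0.003906, the smallest such a test can give, adjusted p = 0.00781 over the 2 components). For the first component that difference was −10.3 ± 14.9 (lower in 6 of 9 pairs, exact p = 0.05469, adjusted p = 0.0547). Control replicate 3 at 48 h stood apart from its group on the first component, at −19.8 against −61.2 and −72.5. On the second component control replicate 2 at 48 h stood apart, at −11.5 against 39.7 and 42.7. It lay below co-culture replicates 1 and 3 at 48 h (−2.60 and −7.58) there.

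**Figure D1:**
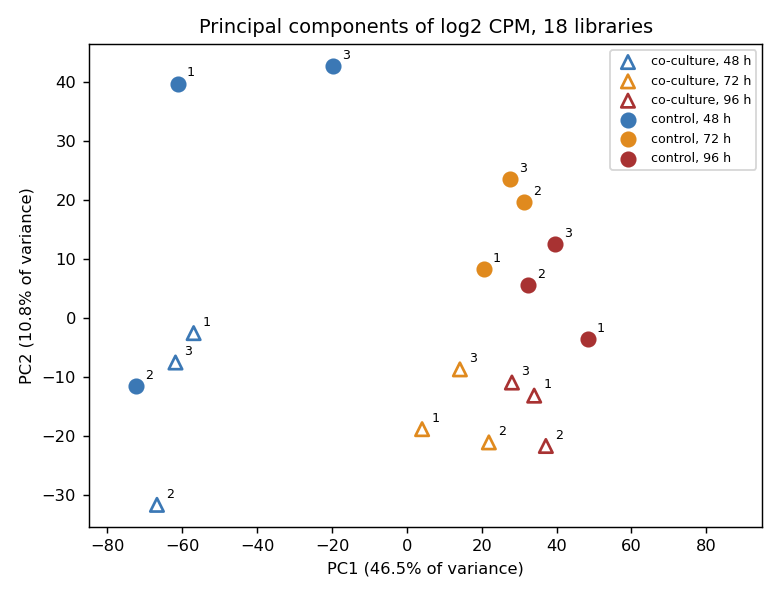
Scores of the 18 libraries on the first component (horizontal, 46.5% of variance) and the second component (vertical, 10.8%) of log2 CPM, with filled circles for control, open triangles for co-culture, colour for time and the replicate number beside each point. The 48 h libraries lie at negative first scores, and co-culture lies lower than control on the second component in 9 of 9 pairs.

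The first question of the design is what the presence of the plant changes in the fungus. Over the mean of the 3 times, pdi1, which encodes a protein disulfide isomerase of the endoplasmic reticulum, fell in co-culture to 956 ± 131 CPM (SD, n = 9) from 1323 ± 213 in control. Its log2 fold change was −0.47 ± 0.11 (SE, adjusted p = 0.0385, edgeR's quasi-likelihood test). CHT1.1, a chitinase gene, fell by 1.28 ± 0.28 on the log2 scale (adjusted p = 0.0272, the same edgeR test) and was lower in 8 of 9 pairs. Its level in co-culture and control was 2.45 ± 0.72 and 9.31 ± 7.83 CPM at 48 h (SD, n = 3), 14.9 ± 4.40 and 34.8 ± 7.80 at 72 h, and 19.02 ± 3.22 and 30.5 ± 5.39 at 96 h. Among called genes with 1 direction in all pairs and a mean of at least 5 CPM, a choice made after the values were seen, the locus tags with the largest differences were TRIVIDRAFT_69268 (log2 fold change 3.46 ± 0.79, adjusted p = 0.0452) and TRIVIDRAFT_46295 (3.32 ± 0.75, adjusted p = 0.0418) upwards in edgeR's test. TRIVIDRAFT_50439 (−3.42 ± 0.71, adjusted p = 0.0272) and TRIVIDRAFT_53789 (−3.24 ± 0.65, adjusted p = 0.0265) lay at the other end in the same edgeR test. The mean pair differences in log2 CPM at 48, 72 and 96 h were 1.18, 5.54 and 4.85 for TRIVIDRAFT_69268, 1.14, 5.41 and 4 for TRIVIDRAFT_46295, −2.90, −4.52 and −2.92 for TRIVIDRAFT_50439 and −5.55, −1.36 and −0.90 for TRIVIDRAFT_53789, so that 48 h carries most of the last.

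Among the 5 tested secretory stress genes, pdi1 fell and 4 did not pass the test. One of these, bip1, which encodes a chaperone of the endoplasmic reticulum, had a log2 fold change of −0.35 ± 0.11 and was lower in 9 of 9 pairs (adjusted p = 0.129 by edgeR over all genes, 0.0148 adjusted over the list alone, for a list made after the symbols were seen), and DESeq2 called it. The group's camera test gave adjusted p = 0.0816, or 0.276 with the estimated correlation of 0.189. Its fry test, which asks whether the genes move one way on balance, gave adjusted p = 0.0296, or 0.0568 with the replicate block. Of the 10 tested chitinase and glucanase genes, CHT1.1 fell and 9 did not pass, with camera adjusted p = 0.137. Adjusted over the list alone, 1 was higher and 2 were lower. ECH2, an endochitinase gene, was the higher one, with a log2 fold change of 0.46 ± 0.13 and higher levels in 9 of 9 pairs (edgeR adjusted p = 0.0816, 0.0166 with the replicate block). TVC1, a chitinase gene, had a log2 fold change of −2.64 ± 0.72 (edgeR adjusted p = 0.0798, 0.0933 with the replicate block). The block for each pair within a time, chosen after the data were seen, called TVC1 (edgeR adjusted p = 0.00038) and ECH2 (0.015). DESeq2 called both too, edgeR called TVC1 without control replicate 2 at 48 h (adjusted p = 0.00376), and it called ECH2 with libraries thinned to the smallest total and without co-culture replicate 1 at 72 h. The mean pair differences of TVC1 in log2 CPM were −3.48, −0.83 and 0.33 at 48, 72 and 96 h, so that 48 h carries its mean. None of the tested 10 G protein and GTPase genes, 3 MAP kinase genes, 5 cyclin-dependent kinase genes and 30 other kinase genes was called by edgeR, with or without the replicate block. Sm1, which encodes a secreted elicitor of plant defence, stood at 3622 ± 2213 CPM in co-culture and 2405 ± 1476 in control (log2 fold change 0.67 ± 0.35, edgeR adjusted p = 0.359). Tex1, a peptaibol synthetase gene, stood at 3.44 ± 2.35 and 5.52 ± 3.45 CPM (−0.69 ± 0.40, edgeR adjusted p = 0.415).

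**Figure D2:**
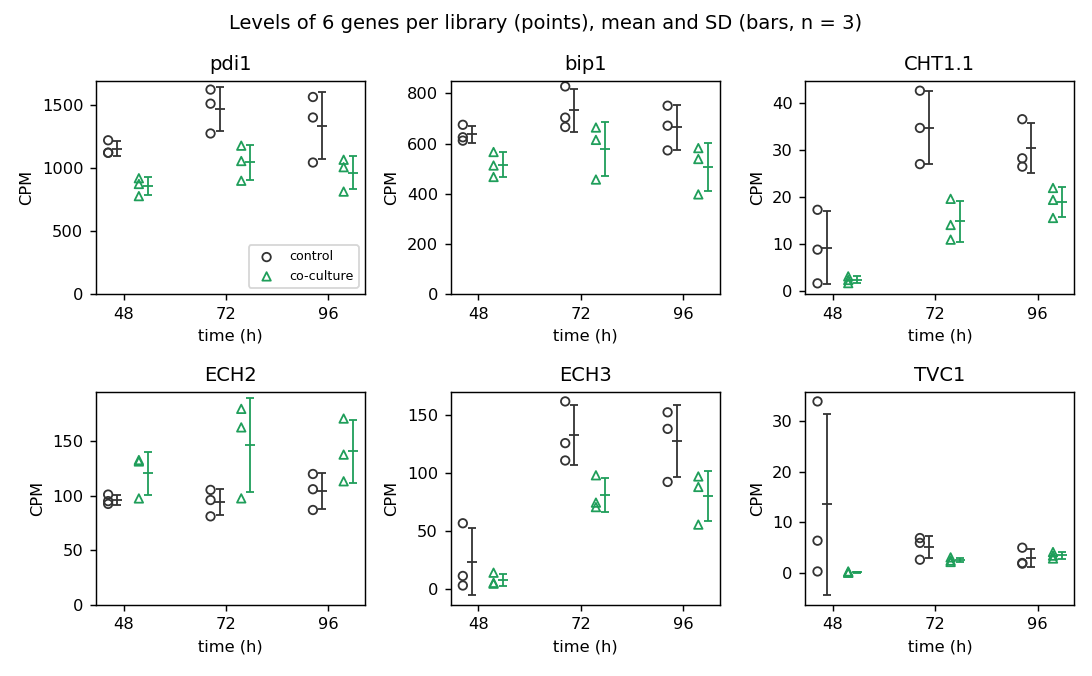
CPM (vertical) of 6 genes at each time in hours (horizontal), with circles for control libraries, triangles for co-culture libraries, and mean ± SD of 3 libraries beside them. The co-culture points of pdi1 lie below the control point of the same number at every time, and CHT1.1 and ECH3 rise from 48 h to 96 h in both conditions.

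In all, edgeR called 147 genes for the mean of the 3 times, 100 higher and 47 lower in co-culture, of which 49 and 29 differed at least 2-fold. With the replicate block there were 256 calls, 168 higher and 88 lower, and 144 genes were called in both fits. With a block for each pair within a time, chosen after the data were seen, there were 508 calls, 283 higher and 225 lower, and 137 of the 147 were among them. TRIVIDRAFT_69268 and TRIVIDRAFT_50439 were not called with the replicate block (edgeR adjusted p = 0.0715 and 0.0511), and with the block for each pair TRIVIDRAFT_69268, TRIVIDRAFT_46295 and TRIVIDRAFT_50439 were not called (edgeR adjusted p = 0.157, 0.133 and 0.0521). DESeq2 called 425 genes, 211 higher and 214 lower, and edgeR without control replicate 2 at 48 h called 455, 188 higher and 267 lower, so that the excess of higher genes was not kept in either. The count was 210 without co-culture replicate 1 at 48 h. It was 66 and 69 without control replicates 1 and 3 at 48 h, 44 without control replicate 2 at 72 h, 50 without control replicate 1 at 96 h, 75 and 49 without co-culture replicates 2 and 3 at 48 h, 89 and 90 without co-culture replicates 1 and 2 at 72 h, and 53 and 82 without co-culture replicates 2 and 3 at 96 h. The call of pdi1 and that of CHT1.1 were each lost in 12 of 18 such fits, with edgeR adjusted p up to 0.0912 and 0.0687 and log2 fold changes from −0.52 to −0.43 and from −1.44 to −1.01. The calls of TRIVIDRAFT_69268 and TRIVIDRAFT_46295 were each lost in 14 of the 18, that of TRIVIDRAFT_50439 in 10 and that of TRIVIDRAFT_53789 in 7. Their log2 fold changes ran from 2.91 to 4.15, 2.83 to 3.92, −4.02 to −3.16 and −3.43 to −2.61. CHT1.1, TRIVIDRAFT_69268 and TRIVIDRAFT_53789 were not called by limma-voom, nor TRIVIDRAFT_46295 by DESeq2. CHT1.1, TRIVIDRAFT_69268 and TRIVIDRAFT_46295 were not called with libraries thinned to the smallest total, nor pdi1, TRIVIDRAFT_69268, TRIVIDRAFT_46295 and TRIVIDRAFT_50439 without the filter on low counts. Reads of the plant were not measured separately in the co-culture libraries.

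**Figure D3:**
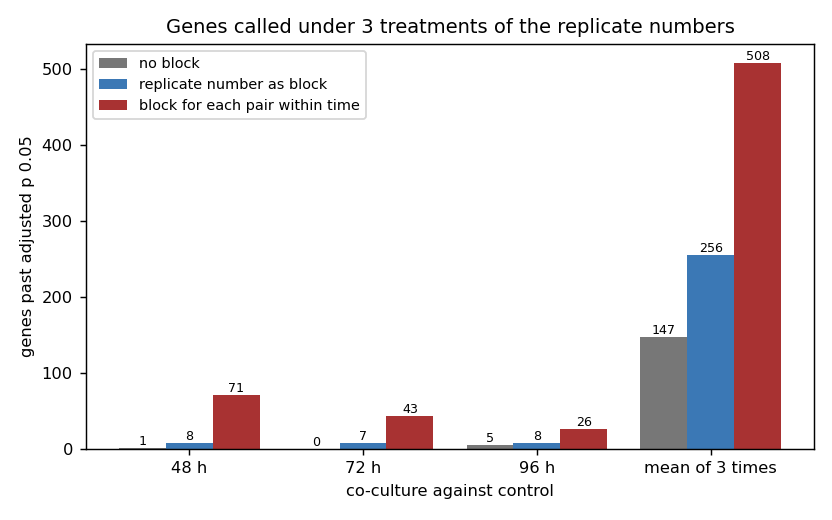
Number of genes past an adjusted p of 0.05 in edgeR's test (vertical) for co-culture against control at each time and for the mean of the 3 times (horizontal), with grey bars for no block, blue bars for the replicate number as a block and red bars for a block for each pair within a time. The counts for the mean are 147, 256 and 508.

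At 48 h, TRIVIDRAFT_181847 fell in co-culture to 48.7 ± 7.20 CPM from 165 ± 62.4 in control (SD, n = 3), a log2 fold change of −1.76 ± 0.25 (adjusted p = 0.0231, edgeR's quasi-likelihood test). Of the 10 tested chitinase and glucanase genes, none was called over all genes by edgeR without a block or with the replicate block, and 2 were lower adjusted over the list alone. These were CHT1.1 (log2 fold change −1.95 ± 0.54, 0.0116 over the list) and TVC1 (0.00265 over the list), in a list made after the symbols were seen. TVC1 had 149, 1 and 42 counts in the control libraries and 1 count over the 3 co-culture libraries, a ratio of 171 (95% counting interval 30.3 to 6780). Leaving out 1 library moved its log2 fold change from −9.06 to −5.14, and that of CHT1.1 from −2.42 to −1.12. Both were called by edgeR without control replicate 2 (adjusted p = 0.000648 and 0.00263) and by DESeq2. The block for each pair within a time, chosen after the data were seen, called TVC1 (log2 fold change −7.02, edgeR adjusted p = 0.000331) and not CHT1.1 (0.057). The replicate block did not call TVC1 (edgeR adjusted p = 0.203). As a group these genes were lower in co-culture by camera (adjusted p = 0.00907), with adjusted p = 0.106 with an estimated correlation and 0.0696 by fry, or 0.0272 by fry with the replicate block. Sm1 (−0.31 ± 0.60) and Tex1 (−1.21 ± 0.68) were not called by edgeR (adjusted p = 0.993 and 0.800).

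That gene was the only call by edgeR at 48 h, against 625 genes at an unadjusted p under 0.05 where chance gives 457, 1 call by limma-voom and 68 by DESeq2. The replicate block gave 8 calls, all lower in co-culture, and the block for each pair 71, of which 7 were higher and 64 lower. Without control replicate 2 the count was 132, and it was 0 without control replicate 1 or 3 or co-culture replicate 2 or 3. The call of TRIVIDRAFT_181847 was lost in 5 of 6 fits that left out 1 library, with edgeR adjusted p up to 0.259.

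At 72 h, Sm1 stood at 3405 ± 2073 CPM in co-culture and 1174 ± 227 in control (SD, n = 3). Its log2 fold change of 1.54 ± 0.62 did not pass the test (adjusted p = 0.475, edgeR's quasi-likelihood test), and it was higher in 3 of 3 pairs. Tex1 stood at 4.90 ± 3.71 and 4.18 ± 2.05 CPM (0.27 ± 0.67, edgeR adjusted p = 0.926). No symbol group shifted by camera, with adjusted p = 0.497 for the chitinase and glucanase genes and 0.0749 for the cyclin-dependent kinase genes. The edgeR test called 0 genes, with 825 at an unadjusted p under 0.05 where chance gives 457, and limma-voom called 0 and DESeq2 41. The replicate block gave 7 calls, all higher in co-culture, and the block for each pair 43, of which 35 were higher and 8 lower.

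At 96 h, TRIVIDRAFT_158830 rose in co-culture to 23.2 ± 6.15 CPM from 1.32 ± 1.29 in control (SD, n = 3), a log2 fold change of 4.19 ± 0.70. TRIVIDRAFT_216348 rose to 233 ± 110 from 43.2 ± 14.4 CPM, by 2.43 ± 0.41 on the log2 scale. The other called genes, named here after their values were seen, were TRIVIDRAFT_230798 (log2 fold change 2.00 ± 0.32), TRIVIDRAFT_78670 (1.96 ± 0.31) and TRIVIDRAFT_119998 (1.38 ± 0.23), and each of the 5 had adjusted p = 0.0411 in edgeR's quasi-likelihood test. Sm1 (0.80 ± 0.61) and Tex1 (−1.14 ± 0.75) were not called (edgeR adjusted p = 0.999 for both), and no symbol group shifted by camera, with adjusted p = 0.0909 for the secretory stress genes and 0.982 for the chitinase and glucanase genes.

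These 5 calls were all higher in co-culture. The replicate block gave 8 calls, 7 higher and 1 lower, and the block for each pair gave 26, 24 higher and 2 lower, while limma-voom called 4 genes and DESeq2 31. The count was 0 with library size as the only scaling, 0 with libraries thinned to the smallest total, and 0 without control replicate 1 or 3 or co-culture replicate 2 or 3. It was 3 without control replicate 2 and 1 without co-culture replicate 1. The calls of TRIVIDRAFT_158830 and TRIVIDRAFT_216348 were each lost in 5 of 6 such fits, with log2 fold changes from 3.81 to 5.24 and from 2.10 to 2.76, and that of TRIVIDRAFT_216348 also with limma-voom and without the filter on low counts.

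The design also asks whether the response to the plant changes over time. No gene was called in that test by edgeR (0 genes, with 143 at an unadjusted p under 0.05 where chance gives 457), limma-voom (0) or DESeq2 (0), and 4 were called by edgeR without control replicate 2 at 48 h. With the replicate block edgeR called 0 too, with 223 at an unadjusted p under 0.05. The block for each pair was not run on this test. Small p-values were fewer than chance gives, so 0 calls do not show that the response stayed constant. Adjusted over the list alone, this F test passed 0 of the 10 tested chitinase and glucanase genes, with or without the replicate block. For TVC1 the co-culture difference was higher at 96 h than at 48 h by 7.25 ± 1.90 on the log2 scale. Its edgeR adjusted p was 1 over all genes and 0.0174 over the list alone. At 72 h against 48 h the latter was 0.0733, and these values were not adjusted over the pairs of times. The log2 fold changes of co-culture against control correlated across the 9144 genes at r = 0.518 between 48 and 72 h, 0.328 between 48 and 96 h and 0.577 between 72 and 96 h. The first fell to 0.298 without control replicate 3 at 72 h, the next to 0.172 without control replicate 3 at 96 h, and the last to 0.451 without co-culture replicate 3 at 96 h. These comparisons share no libraries, and genes are not independent replicates. No gene was called by edgeR at more than 1 time. Its lists (1 gene lower at 48 h, 0 at 72 h and 5 higher at 96 h) allowed no shared call in 1 direction. With the replicate block, 3 genes were called at both 72 and 96 h.

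The comparison of 96 h with 48 h in control shows what changed with the age of the plate without the plant. ECH3, an endochitinase gene, rose to 127 ± 31.4 CPM at 96 h from 23.3 ± 28.9 at 48 h (SD, n = 3), a log2 fold change of 2.42 ± 0.71 (adjusted p = 0.0319, edgeR's quasi-likelihood test). CHT1.1 rose by 1.67 ± 0.46 (edgeR adjusted p = 0.0214), Epl2, a gene of the elicitor family of Sm1, by 2.15 ± 0.66 (0.0406), the kinase gene TPK2 by 0.94 ± 0.20 (0.00411), the regulator gene SKN7 by 0.56 ± 0.15 (0.0143) and CDK5 by 0.61 ± 0.19 (0.0406) on the log2 scale. TVC4, a chitinase gene, fell to 0.490 ± 0.495 from 15.7 ± 8.50 CPM (log2 fold change −4.76 ± 0.73, edgeR adjusted p = 0.000828). The glucanase gene BGN3 (−1.98 ± 0.35), the N-acetylglucosaminidase gene NAG1 (−1.45 ± 0.43) and the kinase gene STK2 (−1.23 ± 0.38) also fell. Of the 10 tested chitinase and glucanase genes, 2 rose, 3 fell and 5 did not pass, or 3 and 5 adjusted over the list alone, and camera gave adjusted p = 0.717. Among locus tags, TRIVIDRAFT_92556 rose to 254 ± 238 from 1.89 ± 2.67 CPM and TRIVIDRAFT_201824 to 43.3 ± 25.0 from 0.478 ± 0.641 CPM. TRIVIDRAFT_51211 and TRIVIDRAFT_8282 fell from 475 and 457 counts over the 3 libraries at 48 h to 1 count each at 96 h, ratios of 445 (95% counting interval 79.4 to 17600) and 428 (76.4 to 16900). The 48 h libraries held 234, 10 and 231 counts of TRIVIDRAFT_51211 and 253, 1 and 203 of TRIVIDRAFT_8282, whose call was lost with DESeq2, with limma-voom and in 4 of 6 fits that left out 1 library. Sm1 (−0.23 ± 0.60) and Tex1 (−0.65 ± 0.65) were not called.

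In co-culture, ECH3 rose from 48 h to 96 h by 3.39 ± 0.76 on the log2 scale (to 79.95 ± 21.9 from 7.67 ± 5.27 CPM, SD, n = 3, adjusted p = 0.00854 in edgeR's quasi-likelihood test). CHT1.1 rose by 2.95 ± 0.54 (edgeR adjusted p = 0.00192), Epl2 by 2.67 ± 0.68 (0.0172), TVC3 by 2.18 ± 0.70 (0.0497), TPK2 by 0.79 ± 0.20 (0.0123) and ire1, a sensor of stress in the endoplasmic reticulum, by 0.52 ± 0.16 (0.0366). BGN3 fell by 1.18 ± 0.36, the kinase gene CSK2B by 0.79 ± 0.22 and TVC4 by 2.02 ± 0.65 (edgeR adjusted p = 0.0372, 0.0233 and 0.0497). Of the 10 tested chitinase and glucanase genes, 3 rose, 2 fell and 5 did not pass, or 4 and 3 adjusted over the list alone, with camera adjusted p = 0.790. TRIVIDRAFT_48802 and TRIVIDRAFT_51553 had 195 and 148 counts at 96 h and 0 at 48 h, at least 76.9-fold and 57.9-fold higher against a floor of 3 counts over the group (0.223 CPM). TRIVIDRAFT_65505 (log2 fold change −5.10 ± 1.15) and TRIVIDRAFT_12229 (−4.27 ± 0.86) fell. TRIVIDRAFT_65505 stood at 130 ± 184 CPM at 48 h and 3.64 ± 0.966 at 96 h, its log2 fold change was −2.67 without co-culture replicate 1 at 48 h, and its call was lost with limma-voom and with only the groups compared. Sm1 (0.89 ± 0.61) and Tex1 (−0.59 ± 0.78) were not called.

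From 48 h to 96 h edgeR called 1405 genes in control, 714 higher and 691 lower, and 1207 in co-culture, 750 higher and 457 lower. Both conditions shared 531 genes that rose, where independent lists would share 58.6, and 299 that fell, where they would share 34.5. No gene was called in opposite directions, and the log2 fold changes correlated at r = 0.822 across genes. The 2 comparisons share no libraries. They are not independent, though, since libraries of the same time and number deviated together across conditions (correlations 0.159 to 0.375 at 48 h and 0.142 to 0.502 at 96 h). Of the 9144 tested genes, 575 were called in control alone and 377 in co-culture alone. The test of a difference between these changes called 0 genes by edgeR (269 at an unadjusted p under 0.05, where chance gives 457), 0 by limma-voom and 0 by DESeq2. The block for each pair was not run on it, and with so few small p-values 0 calls do not show that the changes were equal. Without control replicate 1 at 48 h the count in control was 806, without control replicate 1 at 96 h it was 791, and it was 648 with only these 2 groups fitted. ECH3 in control was not called without control replicate 1 at 48 h, 1 at 96 h or 3 at 96 h, and ire1 in co-culture was not called in any of the 6 fits that left out 1 library. Of such fits, 5 of 6 lost the call of NAG1 and that of STK2 in control and those of BGN3, CSK2B and TVC4 in co-culture, and 4 of 6 that of CDK5 in control and that of TVC3 in co-culture. Epl2 was lost in 3 in control and 2 in co-culture, CHT1.1 and SKN7 in 2 in control, and TPK2 in 1 in co-culture.

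Some of these log2 fold changes moved by over 1.5-fold when 1 library was left out. In control they ran from 1.91 to 4.21 for ECH3 (without replicates 2 and 3 at 48 h), 1.21 to 2.51 for CHT1.1, 1.53 to 2.96 for Epl2, −5.83 to −4.29 for TVC4, 5.84 to 9.38 for TRIVIDRAFT_92556, 5.72 to 8.23 for TRIVIDRAFT_201824, −10.20 to −7.63 for TRIVIDRAFT_51211 and −10.16 to −7.36 for TRIVIDRAFT_8282. In co-culture they ran from 3.11 to 4.09 for ECH3, 2.27 to 3.49 for Epl2, 1.66 to 2.96 for TVC3, −2.98 to −1.56 for TVC4 and −5.36 to −3.87 for TRIVIDRAFT_12229. The calls of STK2 in control and of BGN3, TVC3 and TVC4 in co-culture were also lost with limma-voom. With libraries thinned to the smallest total, those of CDK5, Epl2, NAG1 and STK2 in control and BGN3, ire1, TVC3 and TVC4 in co-culture were lost. With only the groups compared, those of CDK5, CHT1.1, ECH3, Epl2, SKN7 and STK2 in control and BGN3, CSK2B and ire1 in co-culture were lost, and without the filter on low counts those of CDK5, ECH3 and Epl2 in control and ire1, TVC3 and TVC4 in co-culture. Library size as the only scaling lost those of CDK5 and Epl2 in control and ire1 and TVC3 in co-culture, upper quartile scaling those of ire1 and TVC3, and leaving out the 20 most abundant genes that of TVC3. Calls were also gained: NAG1 in co-culture with both these scalings, without the 20 most abundant genes, with DESeq2 and without co-culture replicate 2 at 48 h or 3 at 96 h, TVC3 in control with DESeq2 and without control replicate 3 at 48 h, TVC1 in co-culture with DESeq2 and with only the groups compared, and TVC1 in control without control replicate 2 at 48 h.

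**Figure D4:**
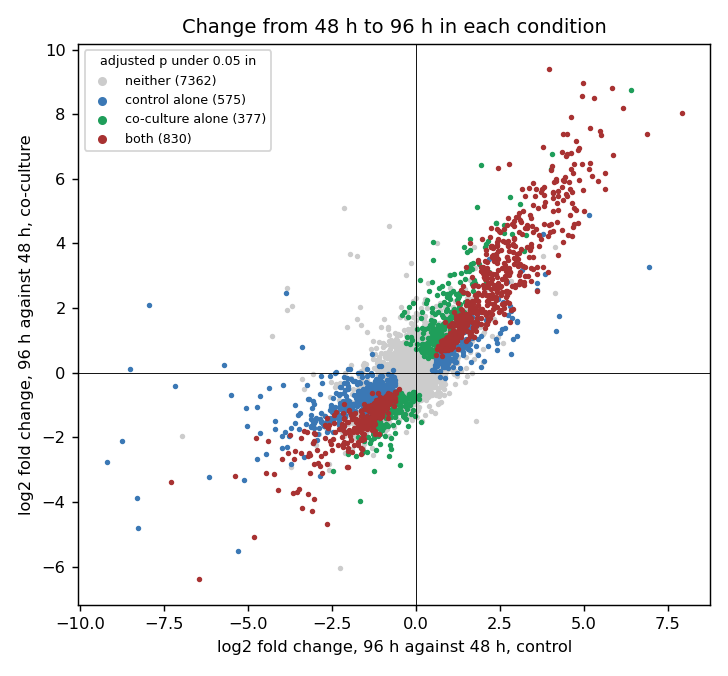
Log2 fold change from 48 h to 96 h in control (horizontal) and in co-culture (vertical) for 9144 genes, coloured by the condition in which edgeR's test called the gene. The 830 genes called in both conditions lie in the quadrants of equal sign.

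More genes were called between 48 and 72 h than between 72 and 96 h. In comparisons chosen after the data were seen, edgeR called 1042 genes from 48 to 72 h in control, 597 higher and 445 lower, and 728 in co-culture, 532 higher and 196 lower. Without control replicates 1 and 2 at 48 h the count in control was 315 and 672, without control replicates 1 and 2 at 72 h it was 689 and 433, and it was 361 with only these 2 groups fitted. Without co-culture replicates 2 and 3 at 48 h the count in co-culture was 404 and 337, and without co-culture replicate 2 at 72 h it was 427. From 72 to 96 h edgeR called 0 genes in control and 0 in co-culture, with 406 and 436 genes at an unadjusted p under 0.05. There DESeq2 called 4 and 9 genes and limma-voom 0 and 3.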

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

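The pairs of the same time and number were compared for 84 genes, 69 with symbols, chosen, like the lists, after the symbols were seen, and 15 locus tags named for their values, and no other test in this part was chosen after its result was seen. TVC1, a chitinase gene, stood out because its co-culture difference changed between times. That difference was higher at 96 h than at 48 h by 7.25 ± 1.90 on the log2 scale. The adjusted p in edgeR's quasi-likelihood test was 0.0174 over its list alone and 1 over all genes. The F test over the 3 times passed 0 of the 10 tested genes of that list, adjusted over the list alone. At 72 h against 48 h edgeR's adjusted p over the list was 0.0733 for TVC1, with no adjustment over the pairs of times. At 48 h its level was 13.5 ± 17.9 CPM in control and 0.0818 ± 0.142 in co-culture (SD, n = 3), with 149, 1 and 42 counts in the control libraries, and at 96 h it was 2.88 ± 1.79 and 3.42 ± 0.64 CPM.

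Another 4 genes stood out because the co-culture library lay above control in each of the 3 pairs at 1 time and below it in each pair at another, a pattern of directions that was not tested in itself. In edgeR's test of the change of the co-culture difference between those times, none of them passed (adjusted p = 1 for each of the 4). For TVC4 the mean difference in log2 CPM rose by 2.20 from 48 h (−0.91) to 96 h (1.29). PAK5 was 1.21 higher at 48 h (0.46) than at 72 h (−0.75), CSK2A was 0.415 higher at 48 h (0.25) than at 96 h (−0.16), and cdc42 was 0.234 higher at 72 h (0.06) than at 96 h (−0.17). Chance alone would give such a pattern in 8.2% of genes, or 5.7 of the 69 with symbols, and 4 of these showed it.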

How the results depend on the processing

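The block for each pair within a time, the alternatives for 72 h with 48 h, for 96 h with 72 h and for differences of the co-culture effect between times, the symbol groups and the leaving out of replicates from correlations were chosen after the data were seen, and the other alternatives given here were planned. No gene followed through the alternatives changed direction where it was called, and the direction of the other called genes was not followed. The excess of higher genes for the mean did not hold with DESeq2 or without control replicate 2 at 48 h. Of the counts that answer a comparison, 210 stayed within 1.5 times their value and 73 moved further. Counts of 0 that stayed at 0 are among the 210. With 1 library left out, counts stayed within 1.5 times in 1 of 6 fits at 48 h, 0 of 6 at 96 h and 7 of 18 for the mean. From 48 to 96 h they did in 4 of 6 in control and 6 of 6 in co-culture. Values of named genes kept their side of the threshold in 976 cases, which include genes not called in either fit, lost a call in 237 and gained one in 27. Of the correlations, 46 moved within their spread and 2 beyond it. Of the counts for differences of the co-culture effect between times, 70 stayed and 2 moved (0 to 2 and 0 to 4 without control replicate 2 at 48 h). The cause was not tested unless given here. With DESeq2 the calls of co-culture against control were 68 at 48 h, 41 at 72 h, 31 at 96 h and 425 for the mean of the 3 times. DESeq2 had 16.2% and 13.4% wrong calls at 48 h and for the mean in simulations with independent genes and unpaired libraries. DESeq2 called 4 genes from 72 to 96 h in control and 9 in co-culture, and limma-voom 3 in co-culture. Between times DESeq2 shared 3 calls (48 and 72 h), 3 (48 and 96 h) and 11 (72 and 96 h), against 0 in edgeR, whose lists allowed none. With the replicate block edgeR gave 8, 7, 8 and 256 calls at 48, 72 and 96 h and for the mean, and 3 shared by 72 and 96 h, as the block took up spread that pairs of libraries share (common biological coefficient of variation 0.26, against 0.296). With the block for each pair it gave 71, 43, 26 and 508 (0.227), TVC1 among those at 48 h and for the mean (edgeR adjusted p = 0.000331 and 0.00038). From 48 to 96 h the replicate block gave 1724 calls in control and 1538 in co-culture. Libraries of the same number correlated there at −0.116, 0.182 and 0.245 in control and 0.199, 0.0707 and 0.178 in co-culture. Whether the numbers shared deviation across these times was not tested, and replicate 1 in control went the other way. The median for other numbers (−0.0895) is no baseline, since deviations cancel out within a group and it mirrors the values of equal numbers. Beyond the changes given in the report, the block changed no call of a gene named there for co-culture against control. From 48 to 96 h, Epl2 in control and TVC3 and TVC4 in co-culture were not called with it (edgeR adjusted p = 0.0726, 0.0578 and 0.0522), and NAG1 in co-culture and NAG2 in control were (0.00332 and 0.0444). An adjusted p under 0.01 left fewer genes by construction: 0 at 48 h, 0 at 96 h, 11 for the mean, 679 and 616 from 48 to 96 h in control and co-culture, and 273 and 273 from 48 to 72 h. A log2 fold change of at least 1 left 78 for the mean. The 96 h count was 0 with library size only, 0 with libraries thinned to the smallest and 0 with only the groups compared, a fit with fewer samples. That fit also gave 0 at 48 h, 648 from 48 to 96 h and 361 from 48 to 72 h in control, and 5 from 72 to 96 h in co-culture. Library size as the only scaling moved the median of all genes from 48 to 72 h in co-culture to −0.10 on the log2 scale. The number of symbol groups shifted at 48 h was 0 with an estimated correlation and 0 by fry, against 1.

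Leaving out each library in turn gave 0 to 132 calls at 48 h, 0 to 3 at 96 h, 44 to 455 for the mean, 0 to 4 for the change with time, 791 to 1572 from 48 to 96 h in control, 315 to 1245 from 48 to 72 h in control, 337 to 621 from 48 to 72 h in co-culture and 0 to 1 from 72 to 96 h in control. It gave 1 to 2 symbol groups at 48 h, 0 to 1 at 72 h and 0 to 1 at 96 h. The correlation of log2 fold changes between 48 and 72 h was 0.298 without control replicate 3 at 72 h, that between 48 and 96 h was 0.172 without control replicate 3 at 96 h, and that between 72 and 96 h was 0.451 without co-culture replicate 3 at 96 h. The gene lists from product names were not run, since the table of genes used here held no column of product names. Depth limits genes of low count: a count of 0 allows 1.22 CPM in the shallowest library. At 48 h edgeR found 20.8% of simulated 2-fold changes, in simulations that did not vary depth.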

Other observations

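Tests chosen after their result was seen were the depth test, the test of plant reads on the lower genes, the bound for mixed RNA, the count of adjacent calls and the tests of a slower time course. Genes that changed with time often stood beside each other in the gene order of the reference assembly. From 48 to 96 h, 8 consecutive tested genes from TRIVIDRAFT_216154 to TRIVIDRAFT_78708 fell together in both conditions, with a median log2 fold change of −1.27 in control and −1.17 in co-culture. In control, 5 consecutive genes from TRIVIDRAFT_218705 to TRIVIDRAFT_52525 rose, with a median of 4.13, and in co-culture 5 from TRIVIDRAFT_195155 to TRIVIDRAFT_66123 rose, with a median of 1.95. These genes were named after their values were seen.

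Adjacent genes called in 1 direction numbered 276 pairs in control and 210 in co-culture, above the highest of 1000 shuffles of the calls (139 and 106), so chance placement is excluded. A small share of one gene's reads counted on its neighbour is argued against by 68 and 48 such pairs with mean CPM within 2-fold of each other, above the highest shuffles (46 and 38). Pairs 2 places apart with an uncalled gene between them numbered 96 and 78, no more than shuffles gave (means 89.8 and 72.4, permutation p = 0.2498 and 0.2847). Reads shared between adjacent genes may therefore account for part of the runs, and runs of genes regulated together would give the same value. No biological explanation was tested.

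Over the mean of the 3 times, 147 genes were called between co-culture and control, which was weighed against reads of the plant and depth. Plant reads counted on genes of the fungus are argued against for the lower genes, since 29 were called at least 2-fold lower. For the higher genes they stay open: the added amounts correlated between genes with a median r of 0.17, between the bounds set for and against. Depth was examined by thinning every library to the smallest total. The 147 genes kept a median of 0.981 of their log2 fold change (quartiles 0.925 and 1.03), and 83 kept their call. The 64 that lost it went from a median size of 0.81 to 0.71 and a median SE of 0.18 to 0.24, a loss of precision. The values show only that the sizes do not depend on unequal totals in the calculation. Thinning keeps each gene's expected share of its library, so the test cannot decide on depth as a cause. A response of the fungus to the plant, which the design names, remains among the open explanations.

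Control replicate 3 at 48 h lay apart from the other 48 h controls. On a scale from the 48 h controls (0) to the 72 h controls (1), its median position was 0.499 over 1237 genes called without it. The other 48 h controls lay at 0.116 and −0.129 and the 72 h controls at 0.917 to 1.12. This argues against a 72 h control library under a wrong label. It does not exclude one, since those other libraries chose the genes, which draws their own positions towards 0 and 1. Co-culture libraries were not placed on the scale. Thinning changed the position of control replicate 3 by −0.00234. That cannot decide on a difference in depth, since thinning keeps each gene's expected share of its library. Mixed RNA of a later plate cannot be told apart: rising and falling genes gave shares of 0.308 and 0.551, a difference of 0.243 that ran from 0.186 to 0.277 when other libraries were left out, around the bound of 0.2. A culture that developed faster was not tested.

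The hypothesis that co-culture slows the time course of the fungus was tested on genes that change with age in control. At 72 h, genes that rose from 48 to 96 h in control had a median log2 difference of −0.40 in co-culture and genes that fell 0.10, a difference of −0.503 (lowest other split −0.38). At 96 h, genes that rose from 48 to 72 h had −0.28 and genes that fell 0.17, a difference of −0.448 (lowest other −0.438). Each was the lowest of 20 splits of the 6 libraries at that time, too few for a share under 0.05. The axis of the 72 h test uses no 72 h library and that of the 96 h test no 96 h library, and the correlation across all genes was −0.0903 and −0.212. The data suggest a slower course in co-culture as a hypothesis, and cannot show it at this number of libraries.

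Other splits of the same libraries were compared with the real ones. For the mean of the 3 times chance is argued against, as far as 100 sampled splits can tell. Of 100 splits within times, 1, the real one, gave as many as 147 genes (highest other 2), as did 1 of 100 that swapped libraries within pairs (highest other 14). For the change with time the real count was 0, which 100 of 100 splits reach by construction (highest other 23), so the splits test nothing there. For the correlation of the co-culture log2 differences in mean log2 CPM between times, 1 of 200 joint splits, the real one, was as high. This argues against chance without excluding it (permutation p = 0.005, the smallest they can give, adjusted p = 0.005 over 3 correlations). The real and highest other values were 0.512 and 0.482 for 48 and 72 h, 0.288 and 0.27 for 48 and 96 h, and 0.592 and 0.452 for 72 and 96 h. Among the 32 joint splits that part all pairs the real one was highest each time, and the highest others were 0.349, 0.244 and 0.452. The splits treat the times as separate, although libraries of the same number also deviated together between 72 and 96 h (correlations 0.203 to 0.313), and the 3 correlations share libraries.

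Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. At 48 h, 5 splits gave as many as the real 1 call, and the highest other gave 127. That split set control replicates 1 and 3 and co-culture replicate 1 against the rest, which include control replicate 2, and parts 1 pair. The first 3 had the highest scores of the 48 h libraries on the second component. That component also differed between the conditions, so the scores cannot part condition from another structure of the samples. What set this split apart was not tested. The splits that part all 3 pairs gave at most 0 besides the real one. At 72 h the real count of 0 is reached by all 10 splits by construction (highest other 1), and at 96 h 1 split gave as many as 5 (highest other 1). For 96 h against 48 h, 1 split gave as many as 1405 in control (highest other 0) and 1 as many as 1207 in co-culture (highest other 0). For 72 h against 48 h, 1 split gave as many as 1042 in control (highest other 11) and 1 as many as 728 in co-culture (highest other 0). For 96 h against 72 h the real counts were 0, again reached by construction by 10 splits in control (highest other 0) and 10 in co-culture (highest other 1). For symbol groups, 4 splits gave as many as 1 at 48 h, and at 72 h and at 96 h the 10 splits reach the real 0 by construction (highest other 1 at each time). Where the real count is 0 the splits say nothing about chance.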
